A study of Homo sapiens and Mus musculus with 5 samples.

How the data were processed

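The deposited tables hold whole-number read counts per fragment and allele, 1 table per cell line, per the file headers with a column for each allele in each RNA library and each plasmid DNA library. The counts are unnormalized: all values are whole and the column totals differ between libraries. Per the labels' protocols, the plasmid library was transfected into each line in triplicate and the input library was amplified from the plasmid pool by PCR before transfection. The protocols call the input and RNA libraries biological replicates, 3 of each, and name no day or batch of transfection. Reads were paired-end and came from polyadenylated RNA reverse-transcribed and amplified in 2 rounds of PCR. The submitters' processing notes name limma 3.40.6 without a model. The aligner, the counting tool and the genome build are not given in the sources used here.

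In the values themselves, an allele kept in a table has at most 1 input library and at most 1 RNA library at 0, and an allele absent from a line's table is written as 0 in all its columns. The same input libraries appear in each table, and their values differ between tables only where 1 of them is 0. PC-12 has RNA replicates 1 and 3, and replicate 2 was not used here. Totals per library were between 5875437 and 10201521 for RNA and between 6380682 and 8421333 for the input. Because PCR reads are not independent molecules, depth bounds the counting error alone. Among the RNA values, 873 were 0 and 43 lay between 1 and 9, and the other RNA libraries of the same line had medians of 544.75 to 4425 counts for the alleles at 0.

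Counts were analysed in R 4.3.3. Library sizes were scaled by the trimmed mean of M values. An allele was tested where its mean count reached 10. The main test was the quasi-likelihood test of edgeR 4.0.16 with Benjamini-Hochberg adjustment over the features of a line, two-sided, at an adjusted p of 0.05. Fragment activity is the log2 ratio of RNA to input of 1 allele, relative to the typical allele of the library, since the scaling sets the middle of the library near 0. The allelic effect is the log2 ratio of RNA to input of allele 2 over that of allele 1, fitted with library, allele and the interaction of allele with RNA. The SE was derived from the estimate and its F statistic. The fits take 1 spread for RNA and input libraries, although the input replicates varied less (r = 0.984 to 0.993 between replicates, 0 left out) than the RNA replicates of a line (0.481 to 0.875). Replicates were also compared by chi-square, and no pair of the same kind agreed within sampling noise: the smallest chi-square per degree of freedom was 14.1.

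Between lines, the overlap of calls was set beside that of independent lists, and effects were compared by Pearson's r, Spearman's rho and covariance, beside 20 simulations of unchanged RNA against the same input. The difference between lines was the interaction of allelic effect and line in 1 fit over 14 libraries and 514 fragments. After centring on the mean of a line, RNA libraries with the same number in different lines deviated together, with r over 0.1 for all 15 such pairs (0.115 to 0.660), but centring alone ties the deviations of replicates 2 and 3 to that of replicate 1. Without centring, the mean r between lines was 0.580 for replicate 1, 0.692 for replicates 2 or 3 and 0.350 for replicate 1 with replicate 2 or 3. Both the replicate number as a block and an allele-by-replicate-1 term were also fitted in that test.

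The choices of tests, alternatives, gene lists and named features were made before the data were examined, except where stated. Named SNPs were, per line, the 5 largest allelic effects in each direction past the threshold with the same sign in all RNA libraries, and the 3 highest and 3 lowest alleles for activity; some of the named features and list members are not reported here. SNPs past the threshold in all 4 lines were to be added, but no allelic effect passed in more than 1. The 5 fragments with the smallest adjusted p for a difference between lines were named as well. Gene lists were the MHC region, voltage-gated calcium channel genes, glutamate receptor genes, synaptic genes, chromatin and transcription factor genes and dopamine genes. A SNP was assigned to the gene containing it, from a table of protein-coding genes of GRCh38.p14, and to genes within 10 kb as an alternative. Of the 327 positions, 220 lay inside such a gene, against a median of 162 and a highest of 189 over 58 copies of the positions shifted by 200 to 3000 kb, and 2 positions lie beyond the end of chromosome 20 in GRCh37. The planned test of base classes was not run because the bases were not used here, nor was that of exons against introns, since the gene table holds no exons.

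The alternatives were DESeq2 1.42.0 for the size factors and for the test, limma-voom with limma 3.58.1, limma on log2 ratios with a pseudocount of 1, a minimum of 50 counts or none, thresholds of 0.01 and 0.1, a fold of at least 1.5, the RNA allele ratio alone, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a joint fit of the 4 lines with and without an allele-by-replicate-1 term, fits within replicate 1 and within replicates 2 and 3, fits without a replicate number in all lines, and alleles with a 0 left out. Correlations that turned on counts of 0 were computed with 0 as 0.5 counts, with 0 left out and by ranks, a rule also set after results were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.

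Each test was run on simulated counts with known changes. With the spread fitted for allelic effects, which was wider than that for fragment activity, 16-fold changes in fragment activity were recovered for 56.1% of changed alleles in Neuro-2a, 81.8% in SH-SY5Y, 36.4% in HEK-293T and 42.4% in PC-12. The share of false calls was at most 6.67% over all comparisons. Input and RNA libraries were drawn independently with the same spread, unlike in the data. These shares thus describe the simulated counts and need not hold for the data. With a biological coefficient of variation of 0.3, 4-fold allelic changes were recovered for 92.5%, 91.0%, 88.1% and 80.6%, where the data had 0.913, 0.683, 0.884 and 0.720.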

Results

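STARR-seq, a reporter assay in which a cloned DNA fragment drives its own transcription, was used to read the enhancer activity of SNP alleles linked to schizophrenia in 4 cell lines. Activity was taken as the abundance of a fragment's RNA relative to its abundance in the plasmid DNA that was transfected. The lines were Neuro-2a, a mouse neuroblastoma line, SH-SY5Y, a human neuroblastoma line, HEK-293T, a human embryonic kidney line, and PC-12, a rat pheochromocytoma line whose organism label reads mouse. The tables covered 347 SNPs, of which 20 were named by rs number and 327 by chromosome and position, in 984 fragments. A SNP was carried by up to 3 fragments, with 50, 100 or 150 bases in front of it and 150, 100 or 50 bases behind it. Alleles are numbered 1 and 2 as in the tables, and their bases were not used here.

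Neuro-2a, SH-SY5Y and HEK-293T each had 3 RNA libraries and PC-12 had 2, numbered 1 and 3, and all lines shared 3 libraries of the plasmid input. The RNA totals were 5875437, 7065140 and 6279476 counts in replicates 1, 2 and 3 of Neuro-2a, 10201521, 7178719 and 7329597 in SH-SY5Y, and 6116805, 7846563 and 7097846 in HEK-293T. In PC-12 they were 7969955 and 7503691. Input totals lay between 6380682 and 8421333. Both alleles of a fragment were present for 534 fragments in Neuro-2a, 601 in SH-SY5Y, 606 in HEK-293T and 635 in PC-12. Counts of 0 stood for 16.4% of the alleles in HEK-293T replicate 2 and 9.85% in PC-12 replicate 3, and for at most 6.80% in the other RNA libraries. Genes beside a SNP are those of GRCh38.p14. The build of the positions is not given in the sources used here, so each gene name holds only if that is the build.

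Which fragments were active was asked first, by setting the RNA of each allele against the input in each line. In Neuro-2a, 60 of 1471 alleles were above the input and 25 below it. Among these the highest was allele 1 of the SNP at position 31997390 of chromosome 3, inside OSBPL10, an oxysterol-binding protein gene, and ZNF860, a zinc finger gene, with a log2 RNA over DNA of 6.53 ± 0.43 (SE, n = 3 RNA libraries). Allele 1 at position 141474289 of chromosome 5, inside the protocadherin gamma cluster of neuronal adhesion genes, followed at 5.81 ± 0.62, and allele 1 at position 89631217 of chromosome 16, inside the dipeptidase gene DPEP1, at 4.03 ± 0.80. The lowest past the threshold were allele 1 at position 102730805 of chromosome 4 in MANBA, which encodes lysosomal beta-mannosidase, at -4.96 ± 0.31, allele 1 at position 198058744 of chromosome 2 in PLCL1, a phospholipase C-like gene, at -3.38 ± 0.24, and allele 1 at position 23421980 of chromosome 4, nearest to the coactivator gene PPARGC1A, at -3.10 ± 0.19. All 6 had the same sign in each of the 3 RNA libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment their adjusted p lay between 0.00413 and 0.0496. The 2 highest of these alleles were rare in the input, with means of 84.3 and 68.3 counts against a median of 3832.3, and 9 of the 60 alleles above the input fell in the lowest 25% of input counts. DESeq2 called 420 alleles in this line and limma-voom 112. The count of 85 rested on single libraries: it was 607 without RNA replicate 1, 151 without RNA replicate 3, and 0 without any 1 of the 3 input libraries.

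By edgeR, SH-SY5Y had the most calls, with 116 of 1562 alleles above the input and 86 below it. PC-12 had more by DESeq2, at 643 against 474, and by limma-voom, at 221 against 186. In SH-SY5Y limma-voom turned the balance, with 72 above and 114 below. Among the alleles past the threshold, the protocadherin gamma allele was again among the highest at 5.78 ± 0.54 (SE, n = 3), with allele 2 at position 84581411 of chromosome 15, nearest to the zinc finger gene ZSCAN2, at 4.56 ± 1.02 and allele 1 at position 40279991 of chromosome 15 in ANKRD63 at 4.49 ± 1.03. For the last 2, RNA replicate 1 stood at 1.40 and 1.11 while replicates 2 and 3 lay between 4.82 and 5.36. The MANBA allele was the lowest past the threshold at -5.27 ± 0.16, with an edgeR Benjamini-Hochberg adjusted p of 0.000150, the smallest in the line. The allele near PPARGC1A stood at -4.59 ± 0.41. Allele 1 at position 55532886 of chromosome 18, in the transcription factor gene TCF4, stood at -4.44 ± 0.49. The count of 202 became 858 without RNA replicate 1 and 3 without any 1 of the 3 input libraries.

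HEK-293T had the fewest calls by each of the 3 tools. EdgeR called 21 of 1561 alleles above the input and 16 below it, DESeq2 called 235 and 136, and limma-voom called 25 and 38, which turns the balance. The highest past the threshold were fragments of PPP2R3A, while other alleles with a larger spread had higher or lower fitted values without passing. PPP2R3A is a gene of a regulatory subunit of protein phosphatase 2A. Allele 2 at position 136050568 of chromosome 3 reached 2.85 ± 0.41 (SE, n = 3) with 100 bases in front and 2.58 ± 0.24 with 150 bases in front. Allele 2 at position 19391511 of chromosome 17, nearest to the extracellular matrix gene MFAP4, followed at 1.85 ± 0.30. The lowest past the threshold were allele 2 of the MANBA SNP at -6.87 ± 0.78, allele 1 at position 163793926 of chromosome 1, nearest to the kinetochore gene NUF2, at -6.40 ± 0.66, and allele 2 at position 19329257 of chromosome 19 in MAU2, which encodes a cohesin loader, at -5.57 ± 0.59. Their edgeR Benjamini-Hochberg adjusted p lay between 0.0242 and 0.0462. The count of 37 became 496 without RNA replicate 1, 165 without RNA replicate 2 and 0 without any 1 of the 3 input libraries.

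In PC-12, 91 of 1614 alleles were above the input and 77 below it. The 2 highest named alleles past the threshold were the protocadherin gamma allele at 5.65 ± 0.29 (SE, n = 2) and the PPP2R3A allele with 100 bases in front at 2.99 ± 0.39. Allele 1 of the MANBA SNP stood at -7.79 ± 0.64 with 150 bases in front and at -5.06 ± 0.79 with 100 bases in front. Allele 1 at position 152943676 of chromosome 5, nearest to NMUR2, a neuromedin U receptor gene, stood at -4.60 ± 0.16. Both RNA libraries had the same sign for each of these, and the edgeR Benjamini-Hochberg adjusted p lay between 0.00477 and 0.0326. The count of 168 became 0 without any 1 of the 3 input libraries. With a single RNA library left it was 1454 without replicate 1 and 1257 without replicate 3, in fits that took the spread from the input libraries alone.

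**Figure D1:**
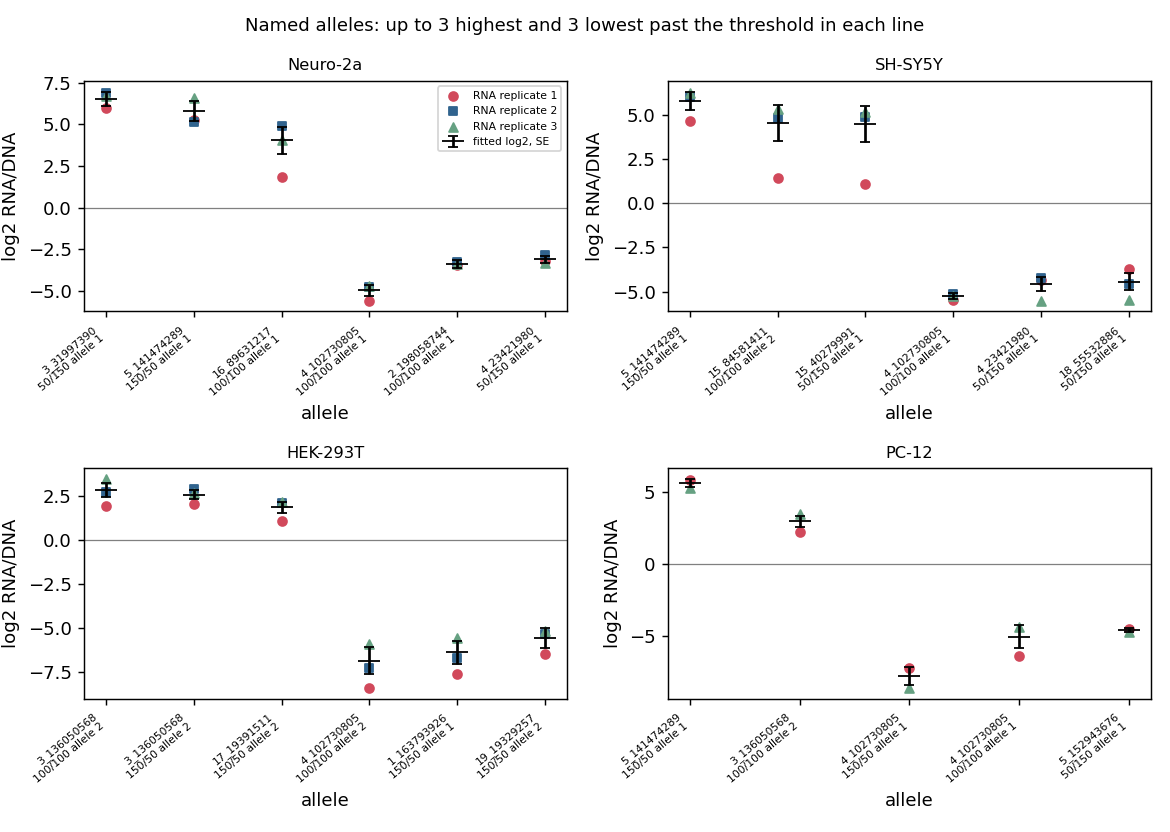
Log2 RNA over plasmid DNA (vertical axis) of the highest and lowest alleles past the threshold in each cell line (horizontal axis), up to 3 of each, with the bases in front of and behind the SNP under each name. Colored symbols are the single RNA libraries and black bars are the fitted value with its SE; the MANBA allele with 100 bases in front stands at -4.96 in Neuro-2a, -5.27 in SH-SY5Y and -5.06 in PC-12.

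The question in the series title, whether the alleles of a SNP differ in activity, was tested as the RNA over DNA of allele 2 relative to that of allele 1. A single fragment passed the threshold in Neuro-2a and another in SH-SY5Y, both with allele 1 more active. In Neuro-2a it was the fragment in OSBPL10 and ZNF860 with 50 bases in front of the SNP, at a log2 allelic effect of -5.83 ± 0.32 (SE, n = 3) and an edgeR Benjamini-Hochberg adjusted p of 0.00266. Its 3 RNA libraries gave -5.70, -5.68 and -6.09. Allele 1 had a mean of 84.3 counts in the input and 5827.7 in the RNA, and allele 2 had 7777.3 and 9614.3, so that the RNA alone held less of allele 1 than of allele 2. Without the input, the log2 ratio of allele 2 to allele 1 in the RNA was 0.71, of the opposite sign and not past the threshold. In SH-SY5Y it was the protocadherin gamma fragment with 150 bases in front, at -6.44 ± 0.51 and an adjusted p of 0.0200. Here allele 1 rose from 68.3 counts in the input to 3354.3 in the RNA while allele 2 had 1496.3 and 964.3.

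Neither effect passed in another line. The OSBPL10 and ZNF860 fragment stood at -3.82 in SH-SY5Y, -3.74 in HEK-293T and -2.18 in PC-12, with edgeR Benjamini-Hochberg adjusted p of 0.620, 0.817 and 0.690. In these 3 lines replicate 1 had the opposite sign. Allele 1 had 0 counts there in SH-SY5Y and in HEK-293T and 71 in PC-12, and between 4674 and 10534 in their other RNA libraries. The protocadherin gamma fragment stood at -7.93 in Neuro-2a, -0.06 in HEK-293T and -10.11 in PC-12, with adjusted p of 0.454, 0.993 and 0.590. Each of these values includes a count of 0, of allele 2 in replicate 1 of Neuro-2a and of PC-12 and of allele 1 in replicate 2 of HEK-293T. Over all fragments, edgeR called 1 of 534 in Neuro-2a, 1 of 601 in SH-SY5Y, 0 of 606 in HEK-293T and 0 of 635 in PC-12. At an unadjusted p under 0.05 the numbers were 58, 81, 25 and 46. DESeq2 called 68, 27, 11 and 68, and limma-voom called 0 in each line. The sign was the same in every RNA library for 34.5% of fragments in Neuro-2a, 40.6% in SH-SY5Y, 33.5% in HEK-293T and 53.5% in PC-12. In 20 simulations of unchanged RNA against the shared input these shares lay between 22.1% and 27.7%, 22.5% and 31.1%, 22.9% and 27.9%, and 47.1% and 53.9%. The simulated RNA libraries were independent. In the data, activity in replicates 2 and 3 correlated at 0.664 in Neuro-2a, 0.850 in SH-SY5Y and 0.617 in HEK-293T, with counts of 0 left out. A share above the simulated range is thus no evidence of allelic effects reproduced in every replicate. PC-12 lay within its range. In simulated counts with the spread of these data, a 16-fold allelic difference was found for 33.3% of changed fragments in Neuro-2a, 72.7% in SH-SY5Y, 30.3% in HEK-293T and 53.0% in PC-12, and a 4-fold difference for at most 17.9%. Most differences of 4-fold or less were thus missed in these simulations. They drew input and RNA libraries independently with the same spread, so the shares found need not hold for the data. Leaving out RNA replicate 1 raised the edgeR counts to 163 in Neuro-2a, 282 in SH-SY5Y and 126 in HEK-293T. In PC-12 it leaves a single RNA library, whose spread comes from the input alone. The SH-SY5Y call was lost without any 1 input library or without RNA replicate 2. A joint fit of all lines with an allele-by-replicate-1 term also gave more calls in each line, for the effect in RNA libraries other than replicate 1.

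Several alleles were called above or below the input in more than 1 line, while edgeR called no allelic effect in more than 1 line. DESeq2 called 21 fragments in at least 2 lines, 20 of them with the same sign, limma-voom called 0, and edgeR at an unadjusted p under 0.05 gave 37. The edgeR count of 0 rose without replicate 1 or without replicate 3 of each line. Such fits leave PC-12 a single RNA library, with its spread taken from the input alone, which inflates its calls. Of the alleles called for activity, 230 were called in 1 line, 68 in 2, 26 in 3 and 12 in all 4. Allele 2 of the PPP2R3A fragment with 100 bases in front stood at 2.98 in Neuro-2a, 3.34 in SH-SY5Y, 2.85 in HEK-293T and 2.99 in PC-12, and allele 2 of that with 150 bases in front at 1.97, 2.94, 2.58 and 2.60 in the same order. Allele 1 of the MANBA fragment with 100 bases in front stood between -5.27 and -4.62 in the 4 lines. For the 6 pairs of lines, between 15 and 67 alleles were called in both, and at most 1 of them in opposite directions. SH-SY5Y and PC-12 shared 38 alleles above the input and 29 below it, where independent lists would share 6.79 and 4.04. The lines share the input libraries and the division of the RNA libraries by replicate number, so independent lists do not give the overlap expected without shared activity. The number of alleles called in at least 2 lines was 106. It also rose without replicate 1 or without replicate 3 of each line, with the same limit for PC-12.

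The allelic effects of the lines were related across fragments, which are not independent replicates. The median Pearson r over the 6 pairs of lines was 0.586, between 0.461 for HEK-293T with PC-12 and 0.708 for Neuro-2a with SH-SY5Y, and the median Spearman rho was 0.631. Between 70.3% and 77.4% of fragments had the same sign in both lines. In 20 simulations of unchanged RNA against the shared input, the median r was 0.00871 and the share of equal signs lay between 49.6% and 50.5%. The median covariance was 1.73 against 0.0146 in the simulations. The simulated RNA libraries were independent between lines, while in the data the activity values of different lines correlated at a mean r of 0.580 between replicates 1 and 0.692 between replicates 2 or 3, against 0.350 between replicate 1 of a line and replicate 2 or 3 of another, with counts of 0 left out. The excess over the simulations is thus no evidence of allelic activity shared between lines. With a different input library for each line of a pair and single RNA libraries, the mean r was 0.734 between replicates 2 or 3 and 0.182 between replicates 1 with counts of 0 left out, and 0.362 and 0.144 with a 0 taken as 0.5 counts. The median r was 0.230 within replicate 1 and 0.497 within replicates 2 and 3, and it fell to 0.20 without replicate 3 and to 0.369 without replicate 2. For fragment activity the median r was 0.817, between 0.788 and 0.904.

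Whether an allelic effect differed between lines was tested with the interaction of allele and line over 514 fragments with both alleles in all 4 tables. None passed by edgeR with Benjamini-Hochberg adjustment, 4 had an unadjusted p under 0.05, and no other tool was run on this test. The smallest p was 0.0130, for a fragment in RAB3IL1, a gene of a Rab3-interacting protein, at position 61919982 of chromosome 11, with allelic effects of -0.79 in Neuro-2a, 0.40 in SH-SY5Y, -0.26 in HEK-293T and 0.18 in PC-12. The next were at position 44743145 of chromosome 5, nearest to the mitochondrial ribosome gene MRPS30, position 66573497 of chromosome 11, nearest to the cathepsin gene CTSF, position 119023381 of chromosome 6 in FAM184A, and position 197393071 of chromosome 2 in the splicing factor gene SF3B1. Near MRPS30 the effect was -2.73 in Neuro-2a and between -0.07 and 0.27 in the other lines. All 5 had an edgeR Benjamini-Hochberg adjusted p of 1.00. The replicate number as a block and an allele-by-replicate-1 term each also left 0. The count was 6 without replicate 1 of each line and 2 without replicate 3. In simulated independent libraries with the spread of these data and 1 line changed, the test found 2.99% of 4-fold and 37.9% of 16-fold differences. The lack of calls is thus no evidence that allelic effects are equal between lines.

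SNPs of gene groups often discussed for schizophrenia were few. None lay in the MHC region or in the dopamine genes listed. Fragments of the synaptic list all came from 3 SNPs in MSRA, a methionine sulfoxide reductase gene. In PC-12, 6 of its 17 alleles were above the input and 0 below it. Allele 2 at position 10388815 of chromosome 8 with 50 bases in front was above the input in each line, at 2.02 in Neuro-2a, 1.49 in SH-SY5Y, 1.19 in HEK-293T and 1.57 in PC-12. The same allele with 150 bases in front was below it in SH-SY5Y at -1.68 and in HEK-293T at -1.75. Of the chromatin and transcription factor list, with SNPs in TCF4, FOXP1 and SP4, only the TCF4 allele 1 with 50 bases in front passed, at -1.90 in Neuro-2a, -4.44 in SH-SY5Y and -3.23 in PC-12. In GRM3, a metabotropic glutamate receptor gene, 1 allele was below the input in SH-SY5Y at -0.71 and another in PC-12 at -0.85. No allele of the calcium channel genes CACNA1C and CACNA2D2 passed in any line.

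Fisher's exact test of these lists against all other alleles with positions gave no call. The smallest p was 0.00608, for the synaptic list in PC-12, with a Benjamini-Hochberg adjusted value of 0.0973 over the lists and lines. The test took the 17 alleles of the 3 SNPs in MSRA as independent, which they are not, so this p may be too small. Adjusted over the list alone, the synaptic list had 3 calls in Neuro-2a, 3 in SH-SY5Y, 3 in HEK-293T and 11 in PC-12, against 2, 3, 2 and 6 over all alleles tested. For allelic effects every list had 0 calls in each line by edgeR, both over all fragments and over the list alone.

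The RNA libraries divided by replicate number more than by cell line. With counts of 0 left out, log2 RNA over DNA across alleles correlated at a mean r of 0.692 between replicates 2 or 3 of different lines and at 0.710 between replicates 2 and 3 of the same line. Replicate 1 of different lines correlated at 0.580. Replicate 1 with replicate 2 or 3 of the same line reached 0.402. With a 0 taken as 0.5 counts the same 4 values were 0.429, 0.371, 0.348 and 0.116. The labels name no batch, so the division was found in the data. Fits over all lines were then made within each set, as a choice made after the data were seen. Over the 514 fragments, the allelic test called 0 with all RNA libraries, 2 in replicate 1 and 110 in replicates 2 and 3 by edgeR, and 0, 26 and 173 by DESeq2. At an unadjusted p under 0.05 the edgeR numbers were 33, 40 and 162. The sets were formed from the agreement of these same libraries. Each fit also took the libraries of a set as independent, although they correlated between lines as given above. The counts within a set are thus no evidence of allelic effects reproduced over lines.

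In the 4 replicate 1 libraries, the fragment near MFAP4 with 100 bases in front had an allelic effect of 1.49 ± 0.07 (SE) with an edgeR Benjamini-Hochberg adjusted p of 0.000265. In replicates 2 and 3 it stood at -0.86, but these libraries were unlike. Allele 2 had 24395 counts in SH-SY5Y replicate 3 and 19442 in HEK-293T replicate 2, against 4482 to 6501 in the others. Allele 1 had 23666 to 35406 counts in these libraries. A fragment at position 52781889 of chromosome 3 in ITIH1, a gene of an inter-alpha-trypsin inhibitor heavy chain, passed in both sets with opposite signs. Its allele 1 had 150 counts over the 3 input libraries against 55927 of allele 2, and 0 in all 4 replicate 1 libraries, where allele 2 had 93644. Taking 3 counts over the group as the floor, RNA over DNA of allele 2 would be at least 83.7-fold higher there. This holds only if the 0 came from sampling of reads. Over all RNA values 873 were 0 and 43 lay between 1 and 9, and the origin of the 0 is not known, so the bound is not firm. In replicates 2 and 3 the effect was -7.41. Of the 110 fragments called in replicates 2 and 3, 59 had the opposite sign in replicate 1, which is 53.6%. Across the 514 fragments the effects of the sets had r = -0.159 and rho = -0.0685, and r was 0.167 with counts of 0 left out. For activity, 181 alleles were called in replicate 1 and 276 in replicates 2 and 3. Of these, 71 were called in both sets, 68 of them with the same sign, where independent lists would share 26.2 with the same sign. Both sets were compared with the same input libraries, which by itself can give shared calls.

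**Figure D2:**
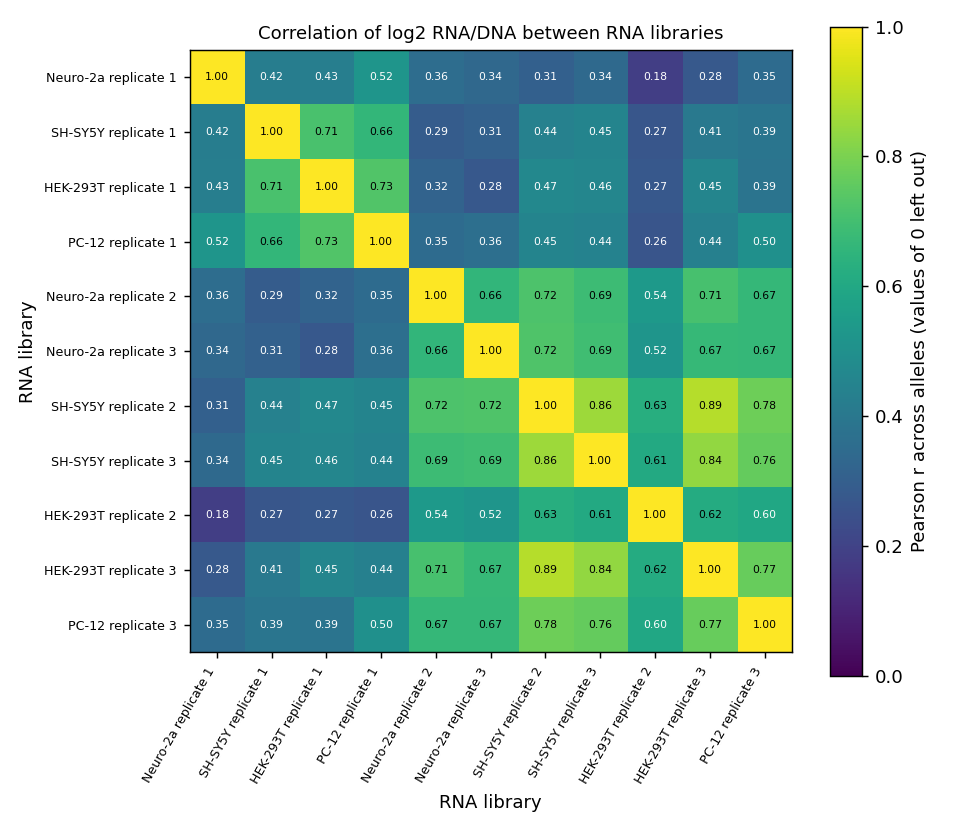
Pearson r of log2 RNA over DNA across alleles between the 11 RNA libraries, with counts of 0 left out; both axes list the libraries, and each cell gives r on a scale from 0 to 1. Replicate 1 libraries of different lines average 0.580 and replicates 2 or 3 of different lines 0.692, against 0.402 for replicate 1 with replicate 2 or 3 of the same line.

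**Figure D3:**
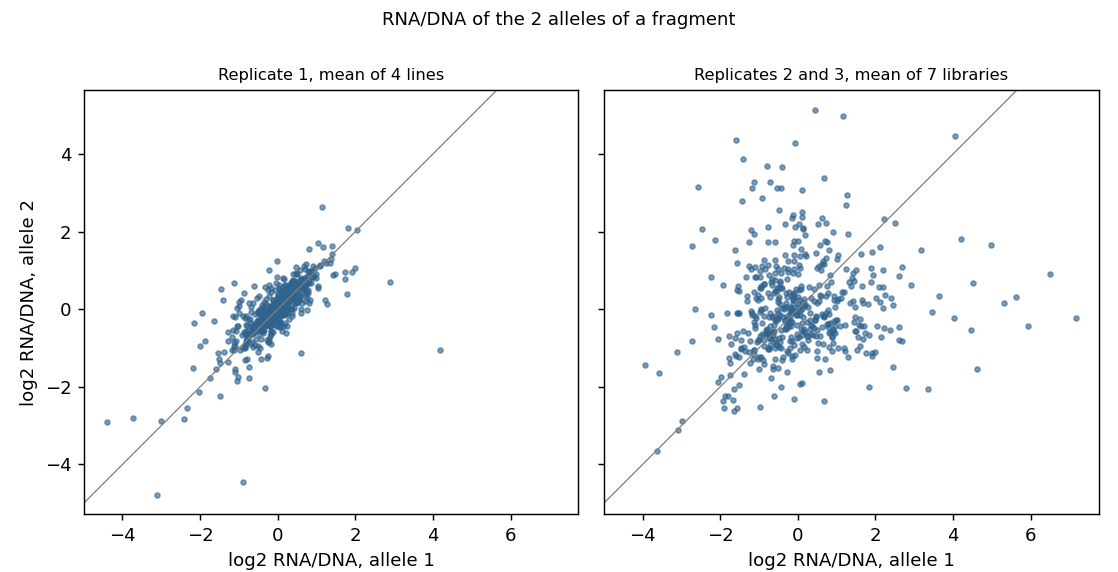
Mean log2 RNA over DNA of allele 1 (horizontal axis) and allele 2 (vertical axis) of the same fragment, 1 point per fragment, in the 4 replicate 1 libraries (left) and the 7 libraries of replicates 2 and 3 (right), with counts of 0 left out; the line marks equal values. The alleles correlate at r = 0.744 in replicate 1 and at 0.136 in replicates 2 and 3.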

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

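No result met the preset criteria for a closer look, and 3 patterns in the libraries are weighed instead. The tests of template composition, fragment sequence (over all fragments and in well-covered ones), sequencing depth, rare alleles and too few counts for the agreement between lines were chosen after the result was seen, as was the rule to compute each test with 0 as 0.5 counts, with 0 left out and by ranks, and to read a verdict only where all 3 agreed; the values given are those with 0 left out.

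Replicates 2 and 3 were alike across lines and unlike replicate 1. If the activity of the sequence caused this, the alleles of a fragment, which share nearly all their bases, should resemble each other there. Their r fell from 0.744 in replicate 1 to 0.136 in replicates 2 and 3, a drop of 0.608 (95% bootstrap interval 0.475 to 0.735). With 0 as 0.5 counts r was only 0.269 (0.118 to 0.413) in replicate 1 and 0.0967 in replicates 2 and 3. The drop was then 0.172 (0.0244 to 0.324), the lowest of the handlings, so the contrast with replicate 1 was weak there. The low r in replicates 2 and 3, found under each handling, argues against activity of the sequence as the sole cause over all fragments. Among 51 fragments with both alleles in the top 25% of input counts r was 0.558 in replicates 2 and 3 (0.274 to 0.776, and 0.448 to 0.558 over the handlings), so activity of the sequence stays open there. A template for replicates 2 and 3 whose allele composition differed from the sequenced input may account for the pattern: it needs a low r between alleles, found at 0.136 over all fragments and undecided in those 51, and a high r between lines, found at 0.692, which was 0.429 with 0 as 0.5 counts, so this stays open. Too few counts would lower the agreement between lines, since counting loss is independent between libraries. Allelic effects of replicates 2 or 3 of different lines, with different input replicates, correlated at a mean r of 0.734 (0.690 to 0.777, lowest of the handlings 0.362). The agreement was known when this test was chosen, and the input replicates come from the same plasmid pool, so its outcome was fixed and adds no support. For the low r between alleles, too few counts stay open. Among the 51 fragments the drop was 0.324 (0.111 to 0.636), and 0.0165 to 0.440 over the handlings. A response of the cells on different days was not tested, because the labels name no batch.

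HEK-293T replicate 2 had 256 alleles at 0, against 16 and 25 in the other RNA libraries of the line. Lower depth is argued against, since its total was 128% of the lower of the other totals. Loss of alleles that are rare in the input may contribute: the share at 0 was 9.44 times higher in the lowest 25% of input counts than in the highest 25%, at 38.6% in the former. A template poor in these alleles stays open, because they lay lower than other alleles in replicates 2 and 3 of the other lines by -0.39 more than in replicate 1 (-0.57 to -0.19), and by up to -1.32 with 0 as 0.5 counts. No biological explanation was tested for this single library.

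Allelic effects of replicate 1 and of replicates 2 and 3 agreed little, with an r of 0.167 that was -0.136 with 0 as 0.5 counts and -0.0602 by ranks. Noise in replicate 1 cannot be excluded: with different input replicates its effects correlated between lines at a mean r of 0.182 (0.102 to 0.279), under the 0.3 set as excluding noise, against the 0.734 above. Allele labels crossed for part of the fragments could give effects of equal size and opposite sign, but sizes correlated at 0.122 (-0.04 to 0.27), which decides neither way, and 53.6% of the fragments called in replicates 2 and 3 had the opposite sign. A different allele composition of the template, as above, also stays open for this pattern. An allelic effect of the cell state was not tested.

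The groups of libraries were also divided in other ways. Of the 10 splits of the 6 libraries of a line into 3 and 3, only the real one, 1 of 10, gave as many calls as the real one for fragment activity in Neuro-2a (85, highest other 0), SH-SY5Y (202, highest other 0) and HEK-293T (37, highest other 0), and for allelic activity in Neuro-2a and SH-SY5Y (1 each, highest other 0). For allelic activity in HEK-293T all 10 of 10 gave 0 calls. With 10 splits no share under 0.05 can be reached. Every other split also puts input and RNA libraries into 1 group, which widens the spread, so the 0 calls there are no support for the real counts. PC-12 had 2 RNA libraries and was not split. For the difference between lines, 100 of 100 assignments of the 11 RNA libraries to the lines gave at least the real count, which a real count of 0 makes certain, so this test and that of allelic activity in HEK-293T decide nothing about chance. The highest other assignment gave 30. It put 3 of the replicate 1 libraries into 1 group, which points to a structure of the libraries by replicate number; with the replicate number as a block the real count was 0.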

How the results depend on the processing

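Tests chosen after the data were seen are the joint fits, the fits without a replicate number in all lines or within replicate sets, and those with alleles at 0 left out. For counts of calls, the order is Neuro-2a first, then SH-SY5Y and HEK-293T, and PC-12 last, and the main counts were 1, 1, 0 and 0 for allelic and 85, 202, 37 and 168 for fragment activity. DESeq2 size factors, no count minimum and a minimum of 50 kept every count within 1.5 times the main one, as did a fold of at least 1.5 for allelic counts. Of the other values of named features, 214 kept direction and call, 121 kept the direction without the call, and 1 reversed: the allelic effect in OSBPL10 and ZNF860 in Neuro-2a was 0.71 from the RNA allele ratio alone (edgeR adjusted p 0.404), which follows from its input counts of 84.3 and 7777.3.

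DESeq2's test called 68, 27, 11 and 68 for allelic and 420, 474, 371 and 643 for fragment activity. Limma-voom called 0 for allelic activity in each line and 112, 186, 63 and 221 for fragment activity, with 72 above and 114 below the input in SH-SY5Y and 25 and 38 in HEK-293T, against 116 and 86, and 21 and 16. The RNA allele ratio alone gave 0 allelic calls in each line. Limma on log2 ratios gave 0 in Neuro-2a, and 1 in SH-SY5Y with allele 2 more active. At an adjusted p of 0.01, fragment counts were 15, 19, 0 and 38 and the allelic count in SH-SY5Y was 0; at 0.1, fragment counts were 178, 412, 105 and 323. The joint fit of all lines gave 0 allelic calls in each. With an allele-by-replicate-1 term it gave 75, 78, 82 and 63, but the effect tested in a line is then that of its RNA libraries other than replicate 1. With alleles at 0 left out, allelic counts were 5, 1, 0 and 0 and fragment counts 159, 327, 95 and 236. All 85, 202, 37 and 168 main calls were also made, but none of these alleles had a 0, so all stayed in the test. The fitted biological coefficient of variation for fragment activity fell from 0.787, 0.608, 0.803 and 0.677 to 0.435, 0.381, 0.445 and 0.373. Whether this accounts for the higher fragment counts was not tested.

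The replicate number as a block gave 0 allelic calls in each line and 0, 1, 0 and 0 for fragment activity. The block leaves fewer residual degrees of freedom, and the reason for the loss of calls was not tested. RNA and input libraries share only a number: of 11 such pairs 1 had r over 0.1, with a mean of 0.0416. In the difference between lines the block gave 0.

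Leaving out each library in turn gave allelic counts of 1 to 163, 0 to 282, 0 to 126 and 0 to 566, and fragment counts of 0 to 607, 3 to 858, 0 to 496 and 0 to 1454. The highest came without RNA replicate 1 in each line, and the lowest fragment counts without any 1 input library, for a reason that was not tested. Without RNA replicate 3 the fragment count was 151 in Neuro-2a and 1257 in PC-12, where the allelic count was 342; a lone PC-12 library is assumed to vary like the input. Without HEK-293T replicate 2 the fragment count was 165. In SH-SY5Y the allelic count was 2 without RNA replicate 3, and 0 without RNA replicate 2 or any 1 input library.

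Without a replicate number in all lines, fragments with allelic calls in at least 2 lines numbered 0 to 311 against 0 (21 by DESeq2 and 0 by limma-voom with all libraries, also chosen after the data were seen), alleles with activity calls in at least 2 lines 152 to 1017 against 106, and fragments differing between lines 0 to 6 against 0; the highest were without replicate 1, and without replicate 3 they were 2, 271 and 2. Activity calls in at least 2 lines were 214 with alleles at 0 left out. Without a filter 8 of 924 fragments differed between lines, each with an allele absent from a table. The median r of allelic effects between lines, 0.586, was 0.20 to 0.497 without a replicate number, with 0.20 without replicate 3 and 0.369 without replicate 2, 0.773 from RNA alone, which keeps the allele ratio of the plasmid pool that the lines share, 0.230 within replicate 1, 0.497 within replicates 2 and 3, 0.652 above median depth and 0.783 with alleles at 0 left out. No gene list passed with genes within 10 kb or with activity calls. The correlation over called fragments was not run because 2 fragments were called, and base classes and other pseudocounts were not run. The input was divided between lines only for single RNA libraries within the replicate sets, where the mean r was 0.734 in replicates 2 and 3 and 0.182 in replicate 1.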

Other observations

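The test of the 3 placements was chosen after the result was seen, and so were the 12 alleles described first. The alleles called for activity in all 4 lines came from 9 SNPs, with 10 alleles above the input and 2 below it. Besides the PPP2R3A, MFAP4, MSRA and MANBA alleles they were alleles in MAD1L1, a spindle checkpoint gene, at position 1977810 of chromosome 7 with a mean log2 RNA over DNA of 1.64, in ANKRD63 at 1.67, in ANKRD27 at position 32672137 of chromosome 19 at 1.17, near ALMS1, a gene of ciliary function, at position 73610828 of chromosome 2 at 1.48, and in PLCL1 at -3.85. For PPP2R3A the fitted values differed between placements. With 50 bases in front of the SNP, allele 2 was below the input in SH-SY5Y at -2.34 and in PC-12 at -1.31. The edgeR Benjamini-Hochberg adjusted p were 0.0103 and 0.0126. In Neuro-2a and HEK-293T this allele stood at -0.54 and -1.88 without passing. These fits pool replicate 1 with replicates 2 and 3, and the difference between placements was not tested. Both alleles of the MANBA SNP with 100 bases in front were below the input in HEK-293T and PC-12, while with 50 bases in front none passed in any line. For PLCL1, allele 1 with 150 bases in front stood at 1.60 in Neuro-2a, 1.55 in SH-SY5Y, 1.38 in HEK-293T and 1.36 in PC-12 without passing in any, but its mean over the replicate 1 libraries was -0.47, against 1.90 in replicates 2 and 3, so the contrast rests mainly on replicates 2 and 3.

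A hypothesis was that fragments near the ends of protein-coding genes are more active, which was tested in the replicate 1 libraries. Of 20 SNPs within 1 kb of a gene end, 18 had an allele in all 4 tables. These 18 had a median log2 RNA over DNA of 0.34 and the other 307 of -0.07. The difference of 0.41 had a two-sided permutation p of 0.00532 and lay between 0.41 and 0.52 over the ways of handling counts of 0. Among the 18, 12 were above 0, against 138 of the 307. The highest lay near LY6H at 1.39, near ALMS1 at 1.05 and near IGSF9B, a gene of inhibitory synapse adhesion, at 0.72, and the lowest were 2 SNPs near FTCDNL1 at -0.56 and -1.12. The gene table used here gives no strand, so promoters and 3' ends were not separated, and the SNPs were not matched on base composition or chromosome. The permutation took SNPs as independent, although some, such as the 2 near FTCDNL1, lie close together.

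A second hypothesis was that the placements of a SNP share its allelic effect in replicate 1. The mean r over the 3 pairs of placements was 0.0935 (95% bootstrap interval 0.00242 to 0.202) with a one-sided permutation p of 0.0612. With 0 as 0.5 counts it was 0.0345 with p 0.267, and by ranks 0.134 with p 0.0141. The handlings disagree, so this stays open. For activity, the placements of a SNP correlated at 0.361 in replicate 1 and at 0.131 in replicates 2 and 3.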
